A study of Homo sapiens with 15 samples.

How the data were processed

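Total RNA from IMR-90 cells, a human fetal lung fibroblast line, was labelled with Cy3 and hybridized to 15 Agilent single-colour arrays on 2 slides. There were 5 groups of 3 arrays, all taken at 48 h: vehicle (DMSO), 50 µM etoposide, 200 µM etoposide, 50 µM etoposide with dominant-negative SRC, and 200 µM etoposide with constitutively active SRC. Per the labels, both SRC forms came from a lentivirus induced with doxycycline. The labels do not say whether the cells without a construct carried a control virus or received doxycycline, so each construct comparison also holds that possible difference. They do not say either whether the replicates were separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

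The values of the scanner files are intensities per the file headers: background-subtracted and detrended within each array by Agilent Feature Extraction 12.0.3.1, with no scaling between arrays. The authors also deposited a matrix in which each value is a score. It was checked against the scanner files and equalled, for each array, the z-score of the logarithm of the processed signal over all 62976 spots, controls included, with a largest difference of 0.005. A nameless last column of that matrix held 16 text cells that name samples of another study, and it was not used.

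Symbols were taken from a RefSeq gene table by transcript accession. Of 58201 probes that were not controls, 33226 had 1 symbol and 24975 had none, and the latter were left out of the main tests. The array grid used an older genome build than the gene table, so genes are given by symbol without coordinates. For each gene the probe with the highest mean signal over all 15 arrays was used. Of 23861 genes with such a probe, 20304 were tested, those whose probe the scanner software called well above the local background on all 3 arrays of at least 1 group. Another 38 symbols had no probe free of spots that the scanner software marked as outliers, and they were left out. Per array, 23508 to 46845 of 60901 spots that were not controls lay well above background and no spot was saturated. The number of arrays limits the precision.

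The processed signal was put on the log2 scale, spots marked as outliers were left out, repeated spots of a probe were averaged, and each array's 75th percentile over its probes was subtracted. A linear model with 5 groups was fitted with limma 3.58.1 in R 4.3.3, with 10 residual degrees of freedom and a prior of 2.22, and two-sided p-values were adjusted by the Benjamini-Hochberg method over the 20304 genes. A gene is called changed at an adjusted p under 0.05, and values after ± are standard errors of the model with 3 arrays per group. For a gene called above background on no array of the lower group, the fold is a lower bound: the lower group's level was raised on each array to at least the lowest level of any probe called well above background there. The comparisons were each etoposide dose against vehicle, 200 µM against 50 µM, each construct against the same dose without it, and the difference between both construct effects.

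Before the data were examined, 20 gene lists were fixed from general knowledge: p53 targets, apoptosis promoters, survival genes, secreted factors of senescent fibroblasts (the senescence-associated secretory phenotype, SASP), mitosis, DNA replication, homologous recombination, polyadenylated histones, NF-kB targets, interferon-stimulated genes, immediate-early and ERK output, integrated stress response, extracellular matrix, YAP and SRF targets, SRC family kinases, cholesterol synthesis, heat shock and chaperones, NRF2 targets, lysosome, and markers of other cell types. The list of SRC family kinases also holds CSK, their negative regulator. The SASP and NF-kB lists share 6 genes, the p53 and apoptosis lists share 5, and 4 other pairs of lists share 1 gene each. A list was called shifted at an adjusted p under 0.05 over the 20 lists from limma's camera, which compares a list with all other genes, with a preset inter-gene correlation of 0.01. The test was repeated with a correlation estimated from the data. Beside it fry was run, which tests whether a list moved in 1 direction, and not against other genes. A list whose members go both ways can fail it although they changed. By fry 17 lists passed at 50 µM, 17 at 200 µM and 14 between doses. With dominant-negative SRC 4 passed, with active SRC 9, and in the constructs' difference 5. Of these, in that order, 7, 3, 5, 0, 3 and 2 did not pass camera. The plot of lists per array shows means, which replaced medians after both were seen.

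The named genes followed a rule fixed at the same time: SRC, a panel of 18 damage, senescence, apoptosis and proliferation genes, the 6 largest rises and 6 largest falls among called genes whose groups did not overlap, and up to 4 called members of each shifted list with up to 2 that went against it. Where 5 or fewer members of a shifted list went against it most are named, those beyond 2 after their values were seen. Whether a construct moved the profile along the difference between doses was measured as a covariance and a correlation across genes. Both differences share arrays, so the covariance was set against 500 simulated draws of unchanged groups that share the same arrays. Genes are not independent replicates, so no p is given for it.

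The alternatives were normexp background correction on the median spot signal, scaling by the median, by the 75th percentile over probes above background on all arrays or by quantiles, the deposited matrix, other filters and probe summaries, slide and replicate number as blocks, other moderation, the groups compared alone, stricter thresholds, and leaving out each array in turn. Array weights, a fit without the 3 arrays with the fewest probes above background, and a test that included probes without a symbol were added after the data were seen. The files held no mean spot signal, hence the median in normexp. The median processed signal of an array was 43.5 to 147, near background, so scaling by the median sets arrays level on dim probes. The pipeline was tested on simulated data with independent noise, with 200 changed genes among 20304 and 18 lysosome genes also raised by a log2 of 0.5. Of the 200 it recovered 31.3% of genes changed by a log2 of 0.5, 67.2% at 1 and 84.8% at 2. Among 134 called genes 5 belonged neither to the 200 nor to the lysosome genes. Far fewer genes changed there than in the real comparisons, so this share of false calls need not carry over to them. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.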

Results

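Gene expression was measured in IMR-90 fibroblasts after 48 h with vehicle, 50 µM etoposide or 200 µM etoposide, and with each dose plus 1 SRC construct. Etoposide is a topoisomerase II poison that breaks DNA, and the series asks how the kinase SRC bears on whether damaged fibroblasts die or become senescent. Each of the 5 groups had 3 arrays. The vehicle and 50 µM arrays and 200 µM replicates 1 and 2 lay on 1 slide, and 200 µM replicate 3 and both construct groups lay on the other. The arrays with the fewest spots well above background were dominant-negative SRC replicate 1 with 23508 of 60901, vehicle replicate 1 with 27453 and 200 µM replicate 2 with 28270. The array of 200 µM replicate 3 had the most spots marked as outliers, 206, and the highest variation between repeated probes, 7.33%. Levels are log2 values relative to each array's 75th percentile.

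The SRC transcript itself, read by a single probe, did not pass the test in any of the 5 comparisons. Its mean level was 1.61 ± 0.11 (SD, n = 3) in vehicle and 1.67 ± 0.07 at 50 µM. The files do not say where the probe lies relative to the cloned SRC sequence, so it may check nothing about the constructs. With dominant-negative SRC the change was 0.17 ± 0.11 (adjusted p = 0.37), and with active SRC it was -0.22 ± 0.11 (adjusted p = 0.20).

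At 50 µM etoposide, against vehicle, the cells showed strong p53 target expression, near loss of cell cycle transcripts and high expression of secreted inflammatory factors, the last a list call lost at an adjusted p = 0.21 with an estimated correlation. CDKN1A, the p53 target that halts the cell cycle, rose 9.38-fold (log2 3.23 ± 0.17, adjusted p = 8.7e-09). LMNB1, the nuclear lamina gene whose loss marks senescent cells, fell by 5.47 ± 0.13 on the log2 scale (adjusted p = 5.6e-12). The chemokine gene CXCL8 rose 7.01-fold and IL6 rose 1.72-fold, a call that ended for IL6 under median scaling (adjusted p = 0.22). Among regulators of apoptosis, BBC3 (PUMA) rose by 1.56 ± 0.07 and BAX by 0.52 ± 0.10 on its brightest probe, though a dimmer probe lay at 0.62 in vehicle and 0.61 at 50 µM and the call ended under 3 of 22 settings (adjusted p up to 0.72), while PMAIP1 (NOXA) decreased by 0.71 ± 0.15 and the survival gene BCL2 decreased by 1.10 ± 0.18. BCL2L1, BCL2L2 and MCL1, which also protect from apoptosis, did not pass, with log2 values of 0.18 ± 0.18, 0.23 ± 0.11 and -0.07 ± 0.09.

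Of 28 measured p53 targets, 26 rose at 50 µM, 1 fell (PMAIP1) and AEN did not pass, with 27 changed adjusted over the list alone (median log2 1.23, camera adjusted p = 1.0e-11). BTG2, an antiproliferative gene, rose by 3.56 ± 0.12 and SPATA18, which acts in mitochondrial quality control, by 3.21 ± 0.10. All 26 mitosis genes fell (median log2 -6.53, adjusted p = 6.6e-35), among them UBE2C, an enzyme of the anaphase-promoting complex, at -8.09 ± 0.11, and CENPA, the centromeric histone, which was at least 203-fold lower. Of 26 DNA replication genes 25 fell (median -3.32, or -3.19 with members below background at their bound, adjusted p = 6.2e-27), and RRM2, a ribonucleotide reductase subunit, decreased by 6.91 ± 0.21. All 15 homologous recombination genes fell (median -4.05, or -3.92 with bounds, adjusted p = 6.0e-17), RAD54L at -6.13 ± 0.17. Adjusted over the list alone, 26, 25 and 15 members of these 3 lists changed. With an estimated correlation, the p53 (adjusted p = 0.018), mitosis (0.0069), replication (0.0069) and recombination (0.017) calls held.

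Of 31 SASP genes, 20 rose at 50 µM, 5 fell and 6 did not pass, with 25 changed adjusted over the list alone (median log2 0.93, adjusted p = 0.00043). IL1B, an inflammatory cytokine, rose by 4.54 ± 0.11 and CXCL1, a neutrophil attractant, by 4.18 ± 0.14, while PLAUR, the urokinase receptor, fell by 1.26 ± 0.12, as did IGFBP3, INHBA and MMP1. Of 23 interferon-stimulated genes 17 rose and 1 fell, 18 adjusted over the list alone (median 0.55, or 0.51 with bounds, adjusted p = 0.0024, adjusted p = 0.18 with an estimated correlation). The interferon median was as low as 0.16 under other settings, the deposited matrix left out. IFI44L rose by 2.38 ± 0.21, and OAS3, an antiviral enzyme, fell by 1.72 ± 0.15. Of 18 lysosome genes 13 rose and 1 fell, 14 adjusted over the list alone (median 0.59, adjusted p = 0.0024, adjusted p = 0.18 with an estimated correlation). FUCA1, a lysosomal fucosidase, rose by 2.46 ± 0.14 and CTSD, the protease cathepsin D, by 0.99 ± 0.17, while GUSB fell by 0.55 ± 0.14. The lysosome call ended under median scaling (adjusted p = 0.051), where 1 member rose, 1 fell and the median was 0.20. The CTSD call ended there too (0.097).

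Cytoskeleton-responsive YAP and SRF targets were lower at 50 µM: 10 of 17 fell and 2 rose, 16 adjusted over the list alone (median log2 -0.41, adjusted p = 0.00014, and 0.037 with an estimated correlation). SRF itself fell by 1.18 ± 0.10 and ANKRD1 by 1.81 ± 0.19. The members that rose were LATS2, a kinase that restrains YAP, at 0.48 ± 0.16 and FHL2 at 0.34 ± 0.13. The LATS2 call ended without vehicle replicate 1 or 50 µM replicate 1 (adjusted p up to 0.10), and that of FHL2 ended without any 1 array but vehicle replicate 2 (up to 0.18). Of 24 immediate-early and ERK output genes 12 fell and 5 rose, 19 adjusted over the list alone (median -0.38, adjusted p = 0.019, adjusted p = 0.080 with an estimated correlation). The AP-1 members diverged: FOSB rose by 2.56 ± 0.21 and FOS by 2.35 ± 0.11, while FOSL1 fell by 1.92 ± 0.18 (ATF3, DUSP1 and PHLDA1 also rose). That list call ended with quantiles (adjusted p = 0.051) and on probes above background on all 15 arrays (0.18). Of 20 integrated stress response genes 10 fell and 5 rose, 15 adjusted over the list alone (median -0.31, adjusted p = 0.044, adjusted p = 0.32 with an estimated correlation). CEBPG fell by 0.69 ± 0.10, and DDIT4, an inhibitor of mTOR signalling, rose by 0.77 ± 0.08, beside SESN2, STC2, NUPR1 and VLDLR, though the DDIT4 call ended under median scaling (adjusted p = 0.21). This last list call was lost under 10 of 21 other settings, among them leaving out vehicle replicate 2 or 50 µM replicate 1 or 2 (highest adjusted p over all settings 0.20).

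The other 10 lists did not pass at 50 µM. Apoptosis promoters had 11 members higher and 4 lower of 21 (adjusted p = 0.17), survival genes 1 higher and 4 lower of 9 (0.11), polyadenylated histones 6 higher and 2 lower of 10 (0.080), and NF-kB targets 10 higher and 4 lower of 20 (0.15). For extracellular matrix genes 17 of 20 did not pass (0.99), and the list test pointed down although its median of 0.03 and mean of 0.08 were positive. SRC family kinases (0.23, median 0.42, or 0.08 with bounds), cholesterol synthesis (0.68), heat shock and chaperones (0.19) and NRF2 targets (0.60, median -0.02 beside a mean of 0.004) did not pass either. Markers of other cell types had 6 of 15 higher and 2 lower (median log2 0.55, or 0.25 with bounds, adjusted p = 0.23).

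Among the largest rises at 50 µM were those of LINC00473, a noncoding RNA, at 7.43 ± 0.22, RGS18 at 4.92 ± 0.20, PDK4, an inhibitor of pyruvate use, at 4.79 ± 0.28, CLCA2 at least 6.3-fold and TREM2 at least 9.9-fold. Large falls were those of SPC25, a kinetochore gene, at least 583-fold, and of H3C15, KIF20A and PBK, at -8.13 ± 0.23, -8.08 ± 0.19 and -8.08 ± 0.17. In all, 10075 of 20304 genes changed by limma, 6142 higher and 3933 lower, and 2231 and 1072 of them by at least 2-fold. The direction split moved with the scaling: 61.0% of changed genes were higher, but 30.0% when arrays were scaled by their median, which moved the median log2 of all genes from 0.19 to -0.20.

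At 200 µM etoposide p53 targets were again high and mitosis, replication and recombination genes low, and most polyadenylated histone genes were higher while matrix and integrated stress response genes were lower than in vehicle. With an estimated correlation the histone and matrix list calls were lost (adjusted p = 0.25 and 0.26). Against vehicle CDKN1A rose 14.7-fold (log2 3.88 ± 0.17, adjusted p = 9.4e-10), GDF15, a stress cytokine, 7.79-fold, and CXCL8 16.7-fold (4.06 ± 0.20). LMNB1 fell by 5.69 ± 0.13. BBC3 rose by 1.53 ± 0.07, and the survival genes went apart: BCL2L1 rose by 0.84 ± 0.18 and BCL2L2 fell by 0.82 ± 0.11, though the BCL2L1 call ended under median scaling (adjusted p = 0.64). BCL2 fell by 0.53 ± 0.18, a call that ended without vehicle replicate 2 or 3 or 200 µM replicate 2 (adjusted p up to 0.079). A dimmer BCL2 probe, above background on 13 arrays and not tested singly, lay at -2.38 in vehicle and -3.87 at 200 µM. IL6 rose by 0.64 ± 0.11, BAX by 0.37 ± 0.10, MCL1 by 0.39 ± 0.09 and PMAIP1 by 0.38 ± 0.15, and all 4 were lower than vehicle, without passing, under median scaling. The PMAIP1 call also ended without vehicle replicate 1 or 3 or 200 µM replicate 1 or 3 (adjusted p up to 0.19).

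Of 28 p53 targets 25 rose at 200 µM and none fell, 25 adjusted over the list alone (median log2 1.49, adjusted p = 1.0e-09, and 0.031 with an estimated correlation). All 26 mitosis genes (median -5.56, adjusted p = 3.3e-23, and 0.025), 25 of 26 replication genes (-3.04, or -2.85 with bounds, adjusted p = 1.3e-18, and 0.025) and all 15 recombination genes (-3.54, adjusted p = 7.3e-12, and 0.031) fell, the second value being that with an estimated correlation. BIRC5 (survivin), active in cell division, fell by 6.84 ± 0.10. Of 21 apoptosis promoters 13 rose and 5 fell, 18 adjusted over the list alone (median 0.52, adjusted p = 0.042, adjusted p = 0.28 with an estimated correlation). The BH3-only genes HRK and BIK rose by 4.28 ± 0.21 and 3.74 ± 0.30 and the death receptor gene TNFRSF10A by 2.41 ± 0.08, while BID and APAF1, which act in mitochondrial apoptosis, fell by 1.08 ± 0.11 and 1.01 ± 0.17, beside CASP8 and CYCS. That list call was lost under 12 of 22 settings, within slide 1 among them (adjusted p = 0.051), and without vehicle replicate 1 or 200 µM replicate 3. Its median turned to -0.18 under median scaling, where its test still pointed up (adjusted p = 0.080).

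Of 31 SASP genes 19 rose at 200 µM and 4 fell, 24 adjusted over the list alone (median log2 0.84, adjusted p = 0.0015, adjusted p = 0.26 with an estimated correlation). The SASP median was as low as 0.15 under other settings, the deposited matrix left out. IL1B rose by 4.87 ± 0.11 and CXCL1 by 4.41 ± 0.14, while IGFBP3, which binds insulin-like growth factors, fell by 1.77 ± 0.09, beside PLAUR and TNFRSF11B. Of 20 NF-kB targets 11 rose and 2 fell (median 0.54, or -0.16 under median scaling, adjusted p = 0.017, adjusted p = 0.37 with an estimated correlation). NFKBIZ rose by 1.66 ± 0.09, while TRAF1 and NFKB1 fell by 0.69 ± 0.13 and 0.59 ± 0.14. Of 23 interferon-stimulated genes 19 rose and 3 fell (median 1.08, or 0.97 with bounds, adjusted p = 0.00059, adjusted p = 0.12 with an estimated correlation), with MX1, an antiviral GTPase, up by 3.02 ± 0.10, OAS3 down at -1.27 ± 0.15 XAF1 at -0.41 ± 0.09 and USP18 lower too, though the OAS3 call ended over the mean of all its probes (0.23) and that of XAF1 with the percentile over probes above background on all arrays (0.13). Of 10 polyadenylated histone genes 8 rose and 1 fell (median 1.05, adjusted p = 0.011, adjusted p = 0.25 with an estimated correlation). H2BC21 rose by 3.65 ± 0.14 and H2BC12 by 2.73 ± 0.11, while H3C4 fell by 2.17 ± 0.12. Of 18 lysosome genes 12 rose and 2 fell (median 0.40, or -0.30 under median scaling, adjusted p = 0.017, adjusted p = 0.26 with an estimated correlation), with FUCA1 up by 2.54 ± 0.14, NPC2 by 1.30 ± 0.10, GUSB at -0.78 ± 0.14 and CTSZ at -0.58 ± 0.14, the CTSZ call ending under 3 of 23 settings (adjusted p up to 0.066). The NF-kB and lysosome calls ended under median scaling (adjusted p = 0.069 and 0.26). Adjusted over the list alone, 14, 22, 9 and 14 members of these last 4 lists changed.

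Integrated stress response genes were lower at 200 µM: 15 of 20 fell and 1 rose (median log2 -0.86, adjusted p = 6.1e-06, and 0.032 with an estimated correlation). PHGDH and PSAT1, enzymes of serine synthesis, fell by 2.03 ± 0.09 and 1.75 ± 0.09 and PCK2 by 2.07 ± 0.15, while DDIT3 (CHOP) rose by 0.35 ± 0.08. Of 17 YAP and SRF targets 13 fell and 1 rose (median -0.57, or -0.56 with bounds, adjusted p = 3.7e-05, and 0.031 with an estimated correlation). CNN1, a smooth muscle actin-binding protein, fell by 3.73 ± 0.50 and SRF by 2.25 ± 0.10, while ANKRD1 rose by 1.03 ± 0.19, a call that ended under median scaling (adjusted p = 0.17). Of 20 extracellular matrix genes 12 fell and 4 rose (median -0.66, adjusted p = 0.0043, adjusted p = 0.26 with an estimated correlation). COL4A1, a basement membrane collagen, fell by 1.94 ± 0.12 and ELN (elastin) by 1.74 ± 0.19, while fibronectin, FN1, rose by 0.69 ± 0.12, beside DCN, COL1A2 and COL6A1, though FN1 and COL6A1 were lower without passing under median scaling. DDIT3 was also lower there, without passing. The COL6A1 call ended without vehicle replicate 2 or 200 µM replicate 1 or 2 (adjusted p up to 0.057). The matrix call ended on the deposited matrix (adjusted p = 0.25) and on probes above background on all 15 arrays (0.066). Of the 10 genes in the SRC family kinase list, CSK included, 6 rose (median 1.00, adjusted p = 0.045, adjusted p = 0.23 with an estimated correlation), with FGR at 4.11 ± 0.23 and LCK at least 4.5-fold, both best known from blood cells. The kinase call was lost under 13 of 22 settings, within slide 1 among them (adjusted p = 0.053), without vehicle replicate 1 or 2 or 200 µM replicate 2 or 3, and on probes above background on all 15 arrays (0.50). Adjusted over the list alone, 16, 14, 16 and 6 members of these 4 lists changed.

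The other 6 lists did not pass at 200 µM. Survival genes had 2 members higher and 4 lower of 9 (adjusted p = 0.38), immediate-early and ERK output 10 higher and 6 lower of 24 (0.91), heat shock and chaperones 4 higher and 2 lower of 11 (0.38), NRF2 targets 2 and 2 of 10 (0.65) and cholesterol synthesis 3 and 1 of 15 (0.96, a test pointing down beside a mean of 0.03). Among markers of other cell types 8 of 15 were higher and 3 lower (median log2 0.74, or 0.16 with bounds, adjusted p = 0.24). Those markers moved apart: the epithelial CDH1 rose by 4.41 ± 0.43 and the endothelial PECAM1 by 3.85 ± 0.20, while the endothelial TEK fell by 1.14 ± 0.10 and the epithelial KRT19 by 0.45 ± 0.08, 4 markers chosen after their values were seen. Among the largest rises were those of CCK, a gut and brain peptide hormone (at least 46.1-fold), CGA, the shared subunit of pituitary and placental hormones (at least 47.4-fold), ADGRV1 (at least 42.9-fold), BFSP2, a lens protein (at least 30.4-fold), and ZNF541 (at least 18.3-fold). LINC00473 rose by 6.82 ± 0.22. Among the largest falls were those of SPC25 at -8.69 ± 0.25, H1-5 at -7.30 ± 0.45 and DEPDC1 at -6.80 ± 0.23. In all, 12952 genes changed, 7322 higher and 5630 lower, and 12520 changed within slide 1. Higher genes made up 56.5% of these, 24.0% under median scaling and 72.5% when the percentile was taken over probes above background on all arrays, with the median log2 of all genes at 0.14, -0.56 and 0.40.

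The responses to both doses overlapped. Of 6142 genes higher at 50 µM, 4378 (71.3%) were also higher at 200 µM, where 2215 would be shared if the calls were independent. Of 3933 lower genes, 3063 (77.9%) were also lower, against 1091. Both comparisons used the same vehicle arrays, which by itself raises the number shared. Across genes the covariance of both changes was 0.934, against 0.0848 as the upper limit of the central range of simulated draws of unchanged groups sharing arrays.

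**Figure D1:**
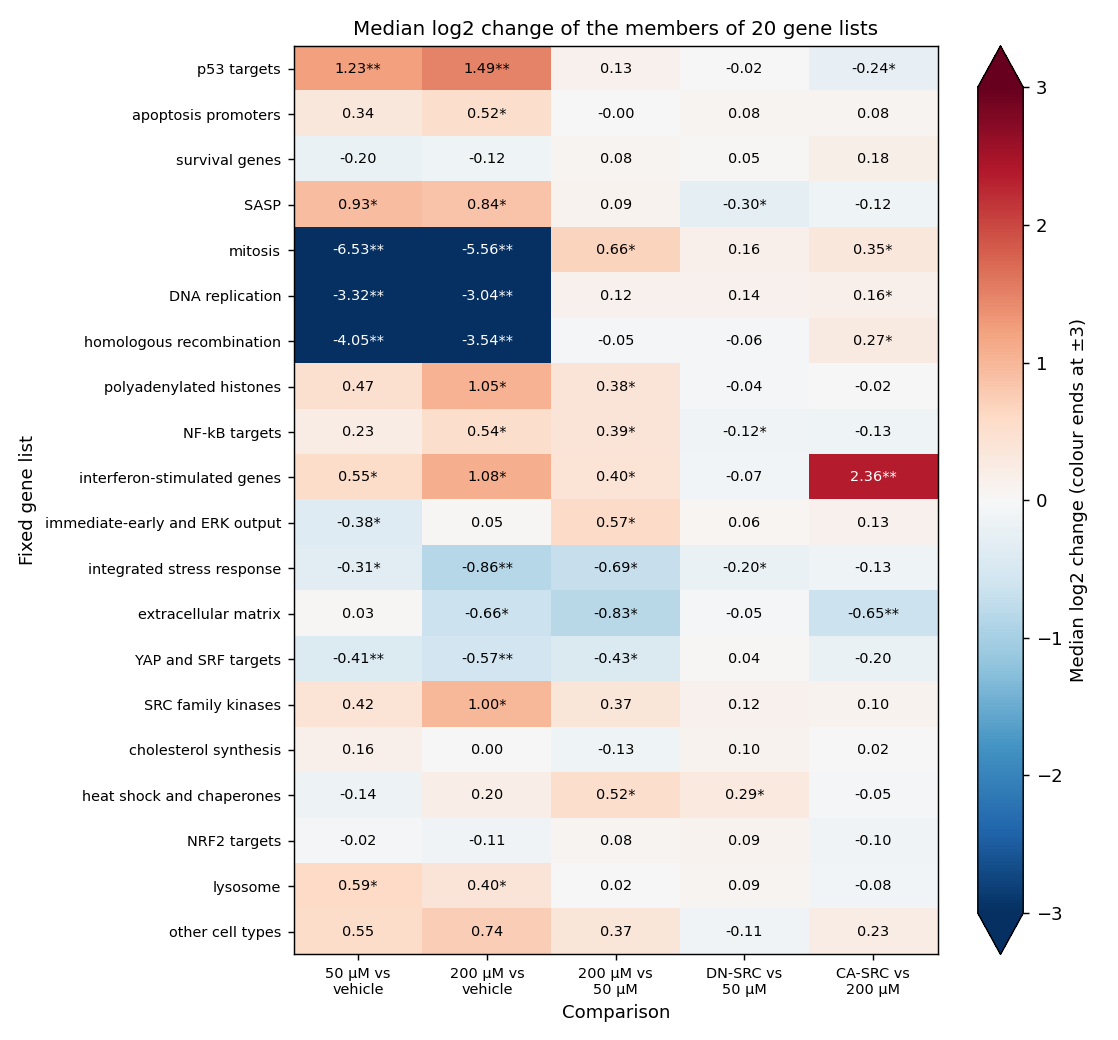
Median log2 change of the 20 fixed gene lists (vertical axis) in the comparisons (horizontal axis), with colours ending at ±3, where * marks a camera adjusted p under 0.05 and ** a call that also held with an estimated correlation. The mitosis median was -6.53 at 50 µM and -5.56 at 200 µM, and that of interferon-stimulated genes was 2.36 with active SRC. Under median scaling the 200 µM medians of apoptosis promoters, NF-kB targets and lysosome turned negative.

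Set against 50 µM, the 200 µM cells had lower matrix and integrated stress response genes, less complete loss of mitosis transcripts and higher heat shock genes. With an estimated correlation none of these 4 list calls held (adjusted p = 0.32, 0.14, 0.35 and 0.32), and under median scaling the heat shock call ended (0.11). The 6768 genes of lowest mean signal were also higher at 200 µM, by a median log2 of 0.32. Under other settings, the deposited matrix left out, the mitosis median was as low as 0.35. PMAIP1 was higher by 1.09 ± 0.15 (adjusted p = 9.0e-05), while BCL2L2 was lower at -1.06 ± 0.11 (adjusted p = 9.8e-06). CXCL8 rose by 1.25 ± 0.20, GDF15 by 0.98 ± 0.10, CDKN1A by 0.65 ± 0.17, BCL2L1 by 0.66 ± 0.18 and MCL1 by 0.46 ± 0.09. The calls of CDKN1A, BCL2L1 and MCL1 ended under median scaling (adjusted p = 0.27, 0.29 and 0.62). TOP2B, the topoisomerase II form that etoposide also poisons, was lower at -0.45 ± 0.11, a call that ended on the deposited matrix (adjusted p = 0.17). BBC3, IL6 and LMNB1 did not pass, with log2 values of -0.03 ± 0.07, -0.15 ± 0.11 and -0.22 ± 0.13. The brightest probes of MDM2 and BAX did not pass either, at -0.01 ± 0.11 and -0.15 ± 0.10, but dimmer probes, not tested singly, were higher: those of MDM2 lay at 0.18 and 1.81 at 50 µM and at 2.03 and 2.75 at 200 µM, and that of BAX at 0.61 and 1.33.

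Of 20 integrated stress response genes 16 were lower at 200 µM than at 50 µM and 2 higher (median log2 -0.69, adjusted p = 1.7e-05, adjusted p = 0.14 with an estimated correlation). PHGDH and PSAT1 fell by 1.52 ± 0.09 and 1.39 ± 0.09, while DDIT3 rose by 0.44 ± 0.08 (ended under median scaling, 0.64) and ATF5 by 0.24 ± 0.08, ATF5 being lower without passing under median scaling and its call ending without 50 µM replicate 2 or 3 or 200 µM replicate 1 or 2 (adjusted p up to 0.081). Of 20 matrix genes 13 fell and 4 rose (median -0.83, adjusted p = 0.00079, adjusted p = 0.32 with an estimated correlation). COL4A1 fell by 2.12 ± 0.12 and COL3A1, a fibrillar collagen, by 1.60 ± 0.14, while FN1 rose by 0.86 ± 0.12 (ended under median scaling, 0.076), beside COL1A2, COL6A1 and TGFBI, the last of which ended without 50 µM replicate 1 or 200 µM replicate 1 or 2 (up to 0.084). Of 17 YAP and SRF targets 11 fell and 1, ANKRD1, rose by 2.84 ± 0.19 (list median -0.43, or -0.31 with bounds, adjusted p = 0.0060, adjusted p = 0.20 with an estimated correlation). Of 26 mitosis genes 16 were higher and 2 lower (median 0.66, or 0.55 with bounds, adjusted p = 0.00024, adjusted p = 0.35 with an estimated correlation). CENPF rose by 1.91 ± 0.15 and BUB1B, a spindle checkpoint kinase, by 1.80 ± 0.14, while CCNA2 (cyclin A2) fell by 0.68 ± 0.12 and AURKA by 0.41 ± 0.10, whose call ended under 2 of 23 settings (adjusted p up to 0.090). Adjusted over the list alone, 18, 18, 13 and 19 members of these 4 lists changed.

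Of 11 heat shock and chaperone genes 7 rose and none fell between the doses (median log2 0.52, adjusted p = 0.0060, adjusted p = 0.32 with an estimated correlation), with the inducible HSP70 genes HSPA1B at 1.39 ± 0.08 and HSPA1A at 0.95 ± 0.12. Of 24 immediate-early and ERK output genes 12 rose and 3 fell (median 0.57, adjusted p = 0.010, adjusted p = 0.14 with an estimated correlation). FOSL1 rose by 1.57 ± 0.18 and SPRY4, a feedback inhibitor of ERK signalling, by 1.24 ± 0.12, while FOS fell by 1.25 ± 0.11, beside MYC and SPRED1, the latter ending without 50 µM replicate 1 or 3 or 200 µM replicate 2 (up to 0.11). Of 20 NF-kB targets 11 rose and 2 fell (median 0.39, adjusted p = 0.016, adjusted p = 0.42 with an estimated correlation), with BIRC3, an inhibitor of apoptosis, up by 2.37 ± 0.18, and NFKB1 and CCL2 at -0.54 ± 0.14 and -0.42 ± 0.07 (CCL2 ended on the deposited matrix, 0.42). Of 10 polyadenylated histone genes 5 rose and none fell (median 0.38, adjusted p = 0.027, adjusted p = 0.35 with an estimated correlation), H1-2 by 0.70 ± 0.11, with H2AC6, H2AC8, H2BC11 and H2BC12, though under median scaling none of the 10 passed. Of 23 interferon-stimulated genes 11 rose and 3 fell (median 0.40, or 0.17 with bounds, adjusted p = 0.034, adjusted p = 0.35 with an estimated correlation), MX1 by 2.25 ± 0.10, with USP18 and XAF1 at -0.64 ± 0.10 and -0.67 ± 0.09. The interferon call was lost under 7 of 22 settings, within slide 1, which is without 200 µM replicate 3, among them (adjusted p = 0.074). On probes above background on all 15 arrays its median was only 0.01, with 5 members higher and 3 lower (adjusted p = 0.061). Without 50 µM replicate 1 the interferon, NF-kB and histone calls were all lost (adjusted p = 0.064, 0.059 and 0.059). Under median scaling these 3 (0.060, 0.18 and 0.30) and the heat shock (0.11), immediate-early and YAP and SRF (both 0.056) calls were lost. With normexp the NF-kB (0.10), histone (0.074), interferon (0.074) and immediate-early (0.058) calls were lost. Adjusted over the list alone, 7, 15, 13, 5 and 14 members of these 5 lists changed.

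The other 11 lists did not differ between doses by the test. p53 targets had 6 members higher and 2 lower of 28 (adjusted p = 0.23), SASP 10 and 7 of 31 (0.60), survival genes 4 and 2 of 9 (0.55) and DNA replication 11 and 4 of 26 (0.20). Apoptosis promoters had 8 higher and 4 lower of 21 (0.33), with a median of -0.003 beside a mean of 0.45. Homologous recombination had 6 and 2 of 15 (0.52), with a median of -0.05 beside a mean of 0.25, and lysosome 6 and 6 of 18 (0.94, a test pointing down beside a median of 0.02). SRC family kinases (0.12), cholesterol synthesis (0.52), NRF2 targets (0.89, median 0.08 beside a mean of -0.01) and markers of other cell types (0.12, median 0.37, or 0.18 with bounds) did not pass either. Among the largest rises of single genes were those of VGF, a neuropeptide precursor, at 4.20 ± 0.08, CYP2F1 at 4.33 ± 0.39, COL2A1, a cartilage collagen, at 4.32 ± 0.65, and PLA2G4D at least 8.4-fold, and the largest falls included EDNRB, an endothelin receptor, at -3.91 ± 0.71, ADH1A at -3.14 ± 0.31 and SGCD at -2.84 ± 0.10. In all 9919 genes differed, 5035 higher and 4884 lower, and 9469 differed within slide 1. Higher genes made up 50.8% of these, 31.3% under median scaling and 68.3% with the percentile over probes above background on all arrays (median log2 of all genes -0.03, -0.33 and 0.15).

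**Figure D2:**
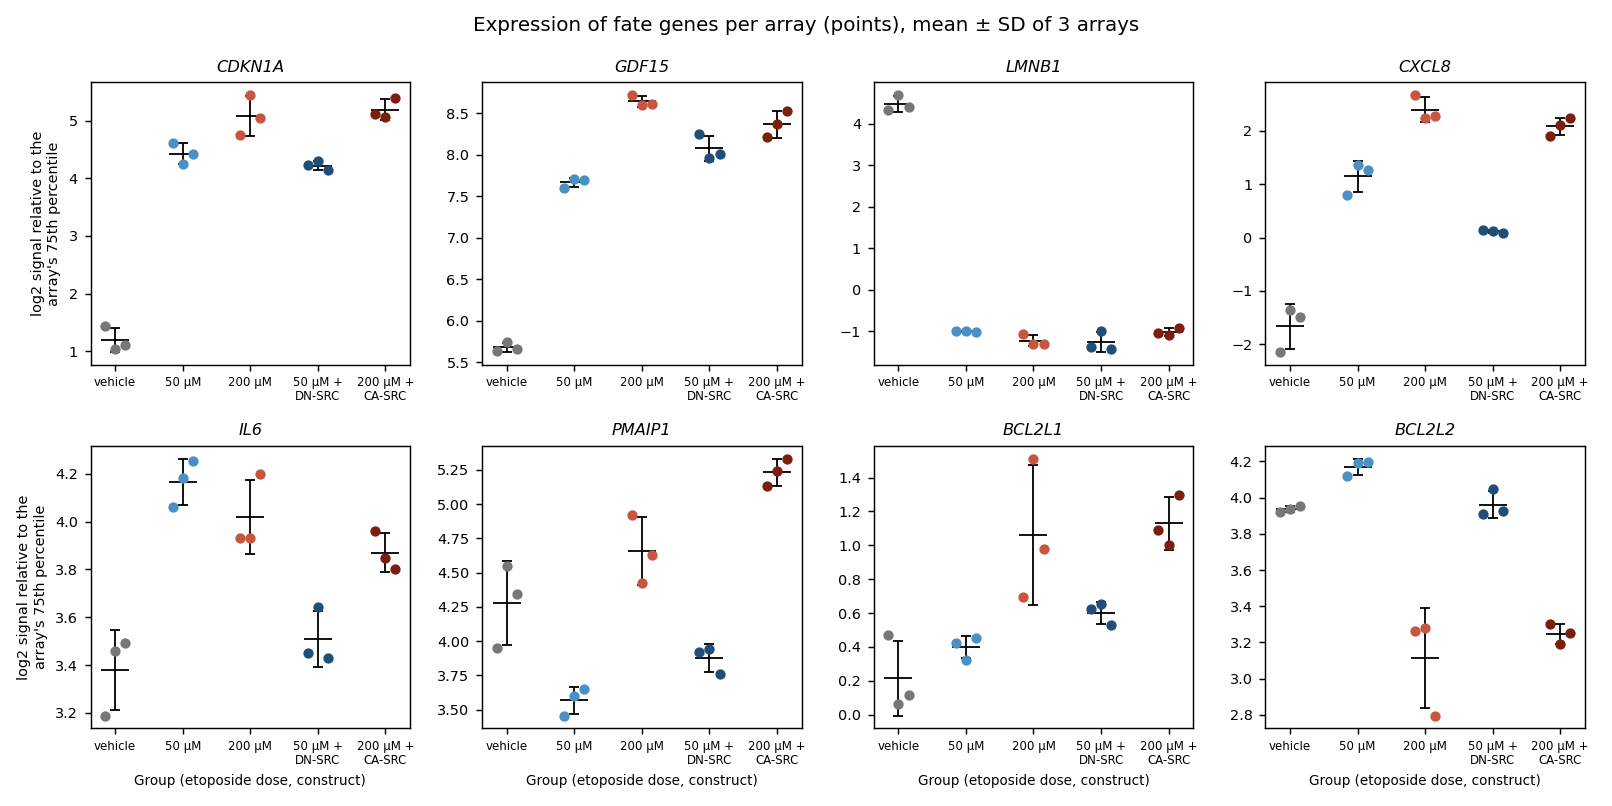
Levels of 8 panel genes on each array (points, log2 relative to the array's 75th percentile) in the 5 groups, with bars for the mean ± SD of 3 arrays. CDKN1A was 3.23 higher at 50 µM and 3.88 higher at 200 µM than in vehicle, and CXCL8 was lower with dominant-negative SRC at -1.03 against 50 µM alone.

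The dominant-negative SRC construct at the low dose went with lower secreted inflammatory factors, a SASP list call that was lost at an adjusted p = 0.62 with an estimated correlation. On probes above background on all 15 arrays that call ended too (0.12), with its median at 0.12. With dominant-negative SRC, against 50 µM alone, CXCL8 fell by 1.03 ± 0.20 (adjusted p = 0.0094) and IL6 by 0.66 ± 0.11 (adjusted p = 0.0037). Of 31 SASP genes 15 fell, 4 rose and 12 did not pass, with 24 changed adjusted over the list alone (median log2 -0.30, adjusted p = 0.0019). The cytokine IL1A was 2.82-fold lower (adjusted p = 0.00086), and the chemokine CXCL2 fell by 1.38 ± 0.15, while MMP1, a collagenase, rose by 0.98 ± 0.14, beside GDF15 and PLAU. LIF rose by 0.49 ± 0.12 and CSF3 fell by 1.48 ± 0.35, calls that ended without any 1 array but dominant-negative SRC replicate 2 for LIF (adjusted p up to 0.11), and without any 50 µM array or dominant-negative SRC replicate 1 for CSF3 (up to 0.10). The GDF15 call ended without replicate 1 or 2 at 50 µM or replicate 1 or 3 with the construct (up to 0.12). The 5 NF-kB targets that fell, of 20 with none higher, included the shared SASP members CXCL1 at -0.98 ± 0.14, CXCL2, CXCL8 and IL6, beside TNFAIP3 (list median -0.12, adjusted p = 0.011, adjusted p = 0.89 with an estimated correlation).

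Of 20 integrated stress response genes 7 fell with dominant-negative SRC and 1 rose (median log2 -0.20, adjusted p = 0.0019, adjusted p = 0.62 with an estimated correlation). DDIT4 fell by 0.76 ± 0.08 and VLDLR, a lipoprotein receptor, by 0.75 ± 0.14, both ending under median scaling (adjusted p = 0.25 and 0.27), while ATF5 rose by 0.35 ± 0.08, a call that ended without 50 µM replicate 1 or 2 or dominant-negative SRC replicate 1 or 3 (adjusted p up to 0.095). Of 11 heat shock genes 4 rose (median 0.29, adjusted p = 0.010, adjusted p = 0.62 with an estimated correlation), with DNAJB1, a co-chaperone of HSP70, at 0.50 ± 0.10, a call that ended without 50 µM replicate 1 or 2 (adjusted p up to 0.059). The calls of the other 3 also ended: HSPE1 without any 1 array (up to 0.14), HSPB1 without any but dominant-negative SRC replicate 2 (0.17), and HSP90AA1 without 50 µM replicate 1 or 2 or dominant-negative SRC replicate 1 or 3 (0.15). Adjusted over the list alone, 5, 9 and 7 members of the NF-kB, stress response and heat shock lists changed. The NF-kB and stress response medians were 0.12 and 0.03 under median scaling, where both tests still pointed down. The NF-kB call ended without 50 µM replicate 3 (adjusted p = 0.092). Under median scaling the SASP median was -0.07 with the call kept at an adjusted p of 1.6e-07, and the calls of CXCL8, CXCL1 and IL6 ended (adjusted p = 0.20, 0.16 and 0.33).

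The other lists did not pass with dominant-negative SRC, though members of some moved both ways. Of 20 matrix genes 2 rose and 4 fell, and of 24 immediate-early and ERK output genes 6 rose and 1 fell. Adjusted over each list alone, 10 members changed in either list. Of 28 p53 targets 2 rose and 1 fell (adjusted p = 0.71), of 21 apoptosis promoters 1 rose and 1 fell (0.98), of 9 survival genes none passed (0.98), and of 26 mitosis genes 5 rose (0.21, median 0.16, or 0.12 with bounds). CDKN1A had a log2 value of -0.21 ± 0.17 (adjusted p = 0.50) and LMNB1 of -0.26 ± 0.13 (0.24). Interferon-stimulated genes had 3 higher and 2 lower of 23 (median -0.07, or -0.06 with bounds, adjusted p = 0.42). For SRC family kinases the median was 0.12 beside a mean of -0.02, and for recombination and histones the tests pointed up beside medians of -0.06 and -0.04. DNA replication (0.12), homologous recombination (0.98), polyadenylated histones (0.98), immediate-early and ERK output (0.73), matrix (0.31), YAP and SRF targets (0.98), SRC family kinases (0.98), cholesterol synthesis (0.79), NRF2 targets (0.61), lysosome (0.71) and markers of other cell types (0.22, median -0.11, or -0.10 with bounds) did not pass. The largest rises included CNTD1 at 1.92 ± 0.31, ATP6V1C2, a proton pump subunit, at 1.81 ± 0.21, and the small nucleolar RNA SNORD37 at 1.48 ± 0.17, and the largest falls the chemokine CXCL6 at -2.34 ± 0.43 (ended with quantiles, 0.081, and slide as a block), ADH1A at -2.25 ± 0.31 and PDK4 at -1.87 ± 0.28.

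In all, 1872 genes changed with dominant-negative SRC, 1208 higher and 664 lower, and 75 and 108 of them by at least 2-fold. The construct and its control lay on different slides, so the slide can be removed only through 200 µM replicate 3: with slide as a block 909 genes changed, SASP stayed called (median log2 -0.60, adjusted p = 0.019), the NF-kB (0.15), stress response (0.15) and heat shock (0.13) calls ended, and so did those of CXCL8 (0.26) and CXCL1 (0.067). Without 50 µM replicate 1 or 2 the count was 702 or 854, and without dominant-negative SRC replicate 1 or 3 it was 712 or 753, and median scaling left 179 and the deposited matrix 421. Higher genes made up 64.5% of the changed genes, 76.5% under median scaling, 46.8% with the percentile over probes above background on all arrays, 50.2% with quantiles and 39.4% on the deposited matrix.

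Active SRC at the high dose went with a large rise of interferon-stimulated genes and a fall of matrix genes. Against 200 µM alone, 22 of 23 interferon-stimulated genes rose and none fell, 22 adjusted over the list alone (median log2 2.36, adjusted p = 1.6e-35, and 0.00023 with an estimated correlation). RSAD2, an antiviral enzyme, rose by 5.84 ± 0.19 (adjusted p = 3.2e-09), IFIT2, which restrains viral translation, by 3.76 ± 0.15, and CMPK2 by 3.79 ± 0.31. Of 20 matrix genes 15 fell and none rose, 16 adjusted over the list alone (median -0.65, adjusted p = 1.5e-12, and 0.035 with an estimated correlation). ELN fell by 2.14 ± 0.19, COL3A1 by 1.43 ± 0.14 and COL5A1, which shapes collagen fibrils, by 1.09 ± 0.10. The mean level of ELN was also lower with dominant-negative SRC, at 0.39 against 1.76 at 50 µM alone.

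Of 28 p53 targets 7 fell and 3 rose with active SRC, 16 adjusted over the list alone (median log2 -0.24, adjusted p = 0.0063, adjusted p = 0.38 with an estimated correlation). SESN2, which responds to stress and restrains mTOR, rose by 0.55 ± 0.11, beside GADD45A and PMAIP1, and its call ended with slide as a block (adjusted p = 0.13) and under median scaling (0.41). BTG2 fell by 0.49 ± 0.12, a call that ended without 200 µM replicate 3 or active SRC replicate 3 (adjusted p up to 0.061) and under median scaling (0.19). Among apoptosis genes PMAIP1 rose by 0.57 ± 0.15 and BBC3 fell by 0.24 ± 0.07, calls that ended without any 1 array but 200 µM replicate 1 for PMAIP1 (adjusted p up to 0.089) and without any 1 array for BBC3 (up to 0.14). Proliferation lists were slightly higher: 9 of 26 mitosis genes (median 0.35, adjusted p = 9.9e-05), 6 of 26 replication genes (0.16, adjusted p = 0.0034) and 3 of 15 recombination genes (0.27, adjusted p = 0.0034) rose and none fell. Over each list alone 12, 10 and 3 rose, and 1 replication gene (TYMS, named after its value was seen) fell. All 3 of these calls were lost at an adjusted p = 0.38 with an estimated correlation. The 6768 genes of lowest mean signal were also higher with active SRC, by a median log2 of 0.26. AURKA, a mitotic kinase, rose by 0.70 ± 0.10 and CDC45, a replication helicase component, by 0.61 ± 0.11, and both ended under median scaling (adjusted p = 0.23 and 0.28), CDC45 also with slide as a block (0.062). Under median scaling the replication call was lost (0.064), and the p53 call was lost with normexp (0.54), with quantiles (0.28) and on probes above background on all 15 arrays (0.17). MKI67, at -0.23 ± 0.12, did not pass.

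SASP genes went both ways with active SRC: 8 rose and 11 fell of 31 (median log2 -0.12, mean 0.05, adjusted p = 0.80). Relative to vehicle, the list's median per array was 1.15 to 1.35 with active SRC and 0.66 to 0.99 at 200 µM alone, while its mean per array overlapped (1.31 to 1.43 and 1.24 to 1.38). IL6 and CXCL8 had values of -0.15 ± 0.11 and -0.31 ± 0.20 and did not pass, nor did CDKN1A at 0.11 ± 0.17. Apoptosis promoters had 2 higher and 2 lower of 21 (0.80), survival genes 1 higher of 9 (0.19), NF-kB targets 1 and 4 of 20 (0.25), and stress response 4 and 8 of 20 (0.054). Histones (0.73), immediate-early and ERK output (0.19), YAP and SRF targets (0.054, median -0.20, or -0.18 with bounds), SRC family kinases (0.97), cholesterol synthesis (0.80), heat shock (0.73), NRF2 targets (0.97), lysosome (0.97) and markers of other cell types (0.25) did not pass. The tests of SRC family kinases and cholesterol synthesis pointed down beside medians of 0.10 and 0.02, and for NRF2 targets and lysosome the medians of -0.10 and -0.08 stood beside means of 0.01 and 0.02. Other large rises were of SPINK1, a protease inhibitor, at 4.17 ± 0.23, the chemokine CCL3 at 3.93 ± 0.54, and the serpin SERPINB4 at least 14.5-fold. The CCL3 probe lay above background on only 4 of all 15 arrays, so the size of its rise is uncertain. Among the largest falls were those of TMEM176B at -2.30 ± 0.19, the adhesion molecule VCAM1 at -2.27 ± 0.23 and MGP, an inhibitor of calcification, at -2.04 ± 0.10. These genes also had lower mean levels with dominant-negative SRC than at 50 µM alone. In that order the levels were 3.35 against 4.28, 3.48 against 4.56 and 2.17 against 3.26.

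In all, 3353 genes changed with active SRC, 1221 higher and 2132 lower, and 187 and 105 of them by at least 2-fold. Within slide 2, against 200 µM replicate 3 alone, whose spread was assumed to be that of the other groups, 2182 genes changed and the interferon and matrix medians were 2.12 and -0.62, with slide as a block 1896 changed, without active SRC replicate 1 or 3 the count was 1504 or 1761, and median scaling left 330 and the deposited matrix 1655. Higher genes made up 36.4% of the changed genes, 59.2% with the percentile over probes above background on all arrays (median log2 of all genes 0.04 and 0.12) and 46.9% with quantiles.

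Calls with both constructs overlapped. Of 664 genes lower with dominant-negative SRC, 213 were also lower with active SRC, where 70 would be shared if the calls were independent. Of 1208 higher genes 206 were also higher, against 73. In opposite directions, 177 were higher with dominant-negative and lower with active SRC, against 127, and 46 the reverse, against 40. Both construct groups shared 1 slide, the virus and doxycycline, while most of their control arrays lay on the other slide. This by itself may raise the number shared in the same direction. Over all genes the construct effects had a correlation of only 0.0616. The construct effects were then tested against each other, each relative to its own dose without a construct. Interferon-stimulated genes moved more with active than with dominant-negative SRC, with 22 of 23 higher, 22 adjusted over the list alone (median log2 2.72, adjusted p = 9.9e-33, and 0.00034 with an estimated correlation). Matrix genes moved lower, 10 of 20 with none higher, 14 adjusted over the list alone (median -0.58, adjusted p = 5.3e-07, adjusted p = 0.19 with an estimated correlation). SASP genes moved higher on balance, 12 up and 8 down of 31, 26 adjusted over the list alone (median 0.37, adjusted p = 0.037, adjusted p = 0.76 with an estimated correlation), though the median was -0.03 under median scaling. The SASP call was lost under 7 of 27 settings, among them without 50 µM replicate 2 or 3, 200 µM replicate 1, dominant-negative SRC replicate 2 or active SRC replicate 2 (adjusted p = 0.061, 0.097, 0.055, 0.058 and 0.057, highest over all settings 0.19). The other 17 lists did not pass, the lowest adjusted p being 0.068 for homologous recombination and for heat shock. In all, 3103 genes differed, 897 higher and 2206 lower. Without 50 µM replicate 1 or 2 the count was 1931 or 1882, without dominant-negative SRC replicate 1 or 3 it was 1725 or 1893, and without active SRC replicate 1 or 3 it was 1465 or 1866. Higher genes made up 28.9%, 58.3% with the percentile over probes above background on all arrays and 46.1% with quantiles.

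**Figure D3:**
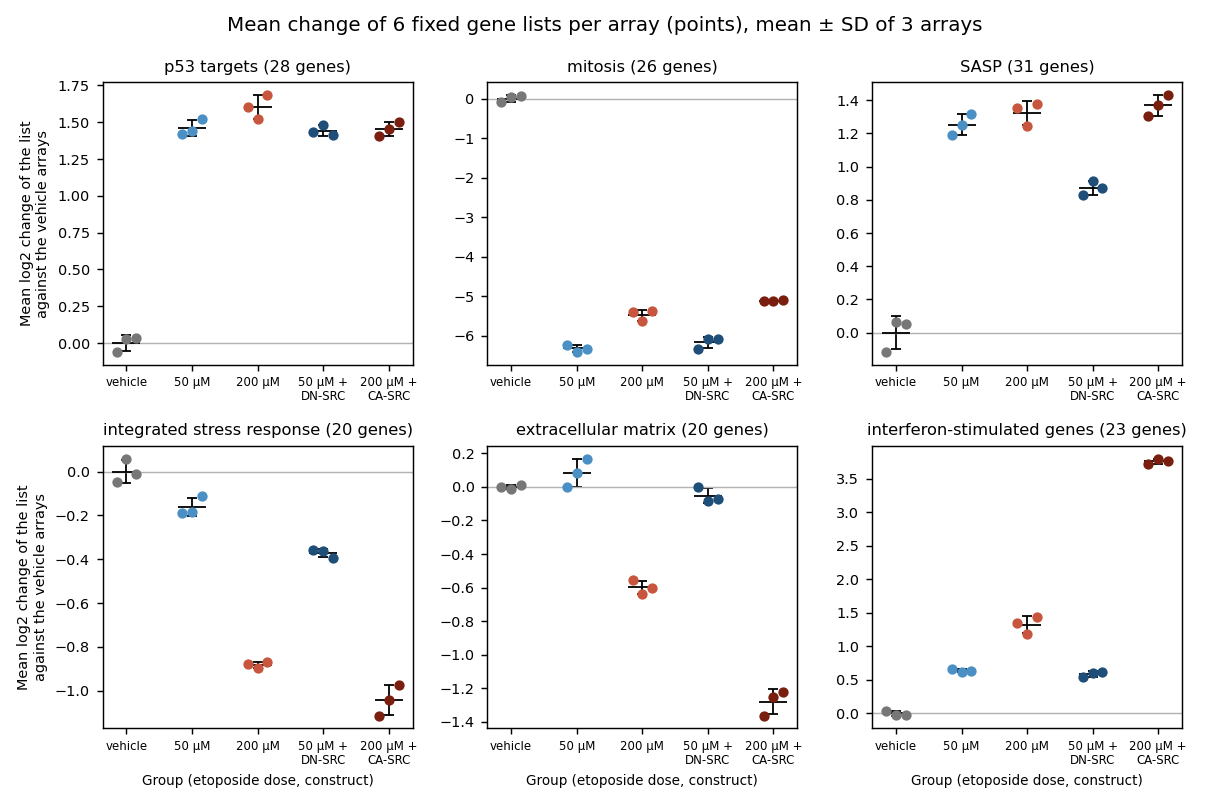
Mean log2 change of 6 gene lists on each array (points) relative to the vehicle arrays, with bars for the mean ± SD of 3 arrays in each group. Interferon-stimulated genes lay at 3.72 to 3.80 with active SRC and at 1.18 to 1.43 at 200 µM alone, and SASP genes lay at 0.83 to 0.91 with dominant-negative SRC and at 1.19 to 1.32 at 50 µM alone.

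Across genes, the change with dominant-negative SRC ran along the difference between 200 µM and 50 µM: the covariance was 0.145, above 0.0848, the upper limit of the central range of simulated draws, whose mean was 0.0316. The correlation, 0.473, lay within the simulated range of -0.08 to 0.83, since both differences share the 50 µM arrays. With those arrays split so that none was shared, the covariance averaged 0.115 (0.0594 to 0.144) and the correlation 0.331. Active SRC did not move the high-dose profile toward the low dose: the covariance with that direction was -0.0701 and the correlation -0.187, or -0.113 and -0.259 with no array shared. Beyond the simulated mean its change ran toward the high dose by 0.102, beside 0.114 for dominant-negative SRC. By this measure the move along the dose difference was therefore not particular to 1 construct.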

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

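The test of virus and doxycycline alone was chosen after the result was seen. A test of the difference between both construct effects picked out 3 lists, as medians over genes of the active SRC effect at 200 µM minus the dominant-negative SRC effect at 50 µM. SASP differed by 0.3675, interferon-stimulated genes by 2.723 and extracellular matrix by -0.5784 (log2). Dose and construct change together in this difference, so it does not part them. Of 100 drawn splits of the 200 possible, 1, the real one, gave as many as 3103 genes, and the highest other gave 606, a share under 0.05. This covers only regroupings of these arrays. Chance between cultures is not covered, since the replicates may not be separate cultures. The real split at the low dose is also the split by slide. For the number of lists chance is not excluded: 55 of the 100 splits shifted at least the real 3, and the highest other shifted 10.

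Interferon-stimulated genes rose with active SRC at 200 µM by a median log2 of 2.36, on all 3 arrays. Virus and doxycycline alone would raise them with dominant-negative SRC too, where their median was -0.07109, a slide effect would vanish within slide 2, where it was 2.121, and a low-quality array would carry it, while without 200 µM replicate 2 it was 2.347. These values argue against all 3 explanations. An effect of the virus together with the 200 µM dose stays open, since no array had virus at that dose without active SRC. That active SRC activity itself may raise these genes at the high dose is a hypothesis that arose from these same data and was not tested.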

How the results depend on the processing

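Array weights, the fit without the 3 arrays with fewest probes above background and the test with unnamed probes were chosen after the data were seen. Weights were estimated gene by gene because the first method did not converge, a change made after counts were seen. Median scaling sets arrays level on dim probes, since the median signal lies near background. Where no reason is given, the cause was not tested. Of named-gene values under other settings, 1521 of 1561 at 50 µM, 2125 of 2173 at 200 µM, 1674 of 1752 between doses, 881 of 1023 with dominant-negative SRC and 1007 of 1138 with active SRC kept direction and side of the threshold.

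Genes changed with dominant-negative SRC, 1872, numbered 1216 with normexp, 179 with median scaling, 421 on the deposited matrix, 909 with slide as a fixed block, 1194 with a replicate block and 8361 with array weights. With active SRC the count of 3353 became 330 with median scaling, 1655 on the deposited matrix, 1896 with slide as a fixed block and 2182 within slide 2, where fewer arrays were compared. For the constructs' difference 3103 became 1869 with normexp, 138 with median scaling, 764 on the deposited matrix and 5385 with array weights. Stricter thresholds lower counts by construction: at least 2-fold left 3303, 5849, 3327, 183, 292 and 586 genes for 50 µM, 200 µM, the doses, dominant-negative SRC, active SRC and the constructs' difference, and an adjusted p under 0.01 left 572, 1349 and 840 for the last 3. Leaving out each array gave, in that order, 8666 to 10105, 11759 to 13049, 8489 to 9469, 702 to 1497, 1504 to 3134 and 1465 to 2966.

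Lists shifted numbered, in the same order, 10, 14, 9, 4, 6 and 3, and 5, 6, 0, 0, 2 and 1 with an estimated inter-gene correlation. Between doses normexp gave 5 and median scaling 3, with dominant-negative SRC the deposited matrix gave 2, probes above background on all 15 arrays 2 and slide as a fixed block 1, and for the constructs' difference normexp gave 6. Without each array they were 9 to 11, 12 to 14, 6 to 9, 4 to 6, 6 to 8 and 2 to 5. The correlation with the dose difference, 0.473 for dominant-negative SRC, was 0.5946 with normexp, 0.3658 with slide as a fixed block and 0.3308 with control arrays split so that none is shared (0.395 to 0.544 without each array). For active SRC it was -0.187, and -0.0623 with normexp, -0.0645 with no filter on dim probes and -0.0642 on probes above background on all 15 arrays (-0.219 to -0.070).

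Median scaling turned 9 named values: FHL2 at 50 µM to -0.048, ATF5 between doses to -0.07, and at 200 µM IL6 to -0.057, PMAIP1 to -0.318, BAX to -0.331, MCL1 to -0.31, DDIT3 to -0.346, FN1 to -0.006 and COL6A1 to -0.318. None of these passed there. Replicate numbers did not in general pair the arrays: of 30 pairs with the same number 5 had a correlation over 0.1 (-0.235 to 0.409). Among these 5 were the pairs of vehicle with dominant-negative SRC, at 0.409, 0.157 and 0.214 for replicates 1, 2 and 3.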

Other observations

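For dim genes the test of scaling, and for the dose direction that of virus and doxycycline alone, were chosen after the result was seen, and the bounds for the background and few-probe tests were made stricter, and the few-probe test narrowed to the dim genes, after their values were seen.

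Genes called at least 2-fold higher at 200 µM than in vehicle were mostly dim: 2844 of 4140 were among the 6768 genes of lowest mean signal. Of these 2844, 1160 lay above background on no vehicle array and 1260 lay above it on all 3 arrays at 200 µM, so no median fold is given. Scaling to the 75th percentile cannot be told apart. Without any scaling all 6768 of these genes, whether or not they rose, had a median of 0.2605 (0.17 to 0.42 without each array), against 0.79 with it. However, a tested gene had to lie above background throughout at least 1 group. Many dim genes may have passed through a treated group, which by itself favours a rise over vehicle. Arrays with few probes above background are argued against, since dim genes called at least 2-fold higher numbered 2904 without the 3 lowest arrays. Higher background cannot be told apart, since negative control spots moved by 0.7257 with a standard error of 0.889, and no biological explanation was tested.

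With dominant-negative SRC the profile moved along the difference between doses, with a covariance 0.114 above the simulated mean. Without 200 µM replicate 3, which takes the slide out of the dose difference, the excess was 0.1186. This argues only against a slide effect that enters through the dose difference. A slide effect in the construct's own change cannot be told apart, since its arrays and their controls lay on different slides. Arrays with few probes above background cannot be told apart, since without 200 µM replicate 2 and dominant-negative SRC replicate 1 the excess was 0.07803, above the limit of 0.0569 set for it by less than a standard error of 0.0499. Virus and doxycycline alone may explain part or all of it: the active SRC change had an excess toward the high dose of 0.1017. Along this 1 direction both excesses were thus alike within the standard errors from leaving out each array, 0.0427 for active and 0.0499 for dominant-negative SRC. Across all genes the construct effects themselves had a correlation of only 0.0616. On probes above background on all 15 arrays the covariance was 0.0888 for dominant-negative SRC. For active SRC it was -0.0127 there with the direction toward the low dose, so little of its move remained. An effect of blocking SRC stays open and untested.

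Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. Counting splits with at least the real number of genes, the real one included, gave 1 at 50 µM (10075, highest other 6), 1 at 200 µM (12952, highest other 3), 1 between doses (9919, highest other 10), 1 with dominant-negative SRC (1872, highest other 1) and 1 with active SRC (3353, highest other 0). For lists shifted they gave 2 (10, highest other 10), 1 (14, highest other 12), 1 (9, highest other 7), 4 (4, highest other 6) and 1 (6, highest other 5).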
